A study of Mus musculus with 8 samples.

How the data were processed

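Hippocampal RNA of C57BL/6J mice labelled male and wildtype was compared between offspring of dexamethasone-injected dams (IUGR) and of saline-injected dams (NS) at postnatal day 3 and week 8, with 2 libraries in each of 4 groups. Per the labels, total RNA was extracted with Trizol, ribosomal RNA was removed with a Ribo-Zero kit, cDNA was made with random primers, and libraries were sequenced in paired ends on an Illumina HiSeq instrument. The treatment group was taken from the treatment labels and the replicate number from the sample titles. The submitters' processing notes name cutadapt 1.16, HISAT2 2.1.0, SAMtools 1.9, featureCounts 1.6.1 and DESeq2 1.26.0 and the mouse genome build mm10. Their order, the annotation release, the strandedness and the handling of reads with several matches are not given in the sources used here. Values of antisense or overlapping genes and of families with near-identical copies, such as ribosomal proteins and histones, are therefore uncertain.

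The authors deposited raw counts of reads per gene symbol in 1 table for each age, each with 24421 genes, and all tests here used these counts. The rows named only genes, every column of counts was matched to a sample, and 3847 genes had no count in any library. The authors' normalized tables hold a signal that is the raw count divided by 1 size factor per library, for genes with at least 2 counts over the 4 libraries of that age (19318 genes at postnatal day 3 and 18868 at week 8), and were only checked against the counts. The gene lengths in the count tables were not used. Total counts ranged from 13030277 to 18993050 per library. A count of 0 is compatible with up to 3 counts, which is between 0.158 and 0.23 CPM, the count scaled by the library total, depending on the library, and such floors and counting intervals cover counting error only. Printed CPM values are raw counts over the library total. The 2 replicates of each group differed far beyond sampling noise (chi-square over genes divided by its degrees of freedom 16.93 and 19.91 at postnatal day 3, 337.3 and 264.93 at week 8), so no library had been entered more than once. Gene positions are those of the GENCODE M21 annotation of GRCm38, the assembly called mm10, in which 24001 of the 24421 symbols were found, 23334 of them under the same symbol.

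The design, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Counts of all 8 libraries were fitted in 1 model of 4 group means with edgeR 4.0.16 in R 4.3.3, with TMM scaling (factors from 0.95 to 1.031) and the default expression filter, which left 15999 genes. Each comparison was tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment, an adjusted p under 0.05 and no minimum fold change. The standard error of a log2 fold change (±, SE) is its size divided by the square root of F. IUGR was compared with NS at each age, the difference between these effects was tested as an interaction, and week 8 was compared with postnatal day 3 in NS. Of 36 gene lists for cell types, pathways and neighbouring tissues, 35 had at least 5 tested genes and were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison; the list of mitochondrial genome mRNAs had too few genes. The call of every list at each IUGR comparison was lost with an estimated correlation and with fry, whose directional p tests whether a list's genes move on balance one way. Overlaps of calls between ages and of calls with lists were tested with Fisher's exact test, which treats genes as independent.

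Named genes were chosen by rule. For each IUGR comparison these were the 10 higher and 10 lower genes with the largest change among those with an adjusted p under 0.05, a mean of at least 1 CPM at that age and no overlap between the 2 IUGR and the 2 NS libraries, leaving out unnamed gene models and small RNAs, with fewer if fewer passed. From each called list up to 4 passing members were added, or up to 2 with the smallest p where none passed, and Tet1 and Nr3c1 were always given. For the difference between ages the 10 genes with the smallest p were taken, and for development 5 higher and 5 lower genes and up to 3 passing members per list, of which the text gives the first ones. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen.

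Alternatives fixed beforehand were other scaling factors (RLE, upper quartile), no count filter or a mean of at least 10 counts, a minimum absolute log2 fold change of 1, DESeq2 1.42.0, limma voom, the replicate number as a block, edgeR and camera on each age alone, the estimated correlation, fry, and each library left out in turn, where a group left with 1 library is assumed to vary like the others. Added after the data were seen were DESeq2 on each age alone, with and without the block, edgeR and camera on each age alone with the block or the estimated correlation, both replicate 2 libraries of an age left out, and crossed replicate numbers at postnatal day 3. An adjusted p that DESeq2 left undefined stayed undefined. The replicate numbers of the titles are not said to mark litters or batches. They were not taken as pairs, but values within each number are given because the week 8 libraries split by number and the postnatal day 3 libraries differ in sex-linked transcripts by number.

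The edgeR fit of all libraries, and the DESeq2 fits of each age alone with and without the block, were tested on simulated counts. So were the edgeR fits of postnatal day 3 alone and of week 8 alone with the block. There were 5 data sets with 200 genes changed 2-, 4-, 8- or 16-fold, at the depths of these libraries. Means were those of each age, of all libraries for development, and of each replicate number for week 8 alone. Data for the fit of all libraries therefore carried the week 8 split by number only as independent noise. The recovery and false calls of that fit may differ on the real libraries. The other fits were not tested on simulated counts. False calls made up 5.6% of the edgeR calls in all libraries for IUGR at postnatal day 3 (15764 genes), 5.7% at week 8 (15766), 6.6% for the difference between ages (15764) and 4.9% for development (15726). With postnatal day 3 alone they made up 10.1% of DESeq2 calls (15435 genes) and 10.6% of edgeR calls (15228). The camera test with the preset correlation called the meninges list in 4 of 5 data sets when its genes were changed 1.5-fold and in 5 of 5 at 2-fold. It called 2 of 170 other lists at each fold. With an estimated correlation it called the list in 0 and 2 of 5 and 0 of 170 others. Simulated genes were drawn independently of each other, so these counts do not cover lists whose genes move together. They cannot show how often the preset correlation gives false list calls here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.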

Results

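RNA was sequenced from the hippocampus of C57BL/6J mouse offspring whose mothers had received dexamethasone or saline late in pregnancy. Dexamethasone is a synthetic glucocorticoid, and the labels name the offspring of treated dams IUGR, for intrauterine growth retardation, and those of saline-injected dams NS, for normal saline. Dams were allocated at random, and the daily intraperitoneal dose of 1 mg/kg was given for 5 days from 14.5 days post coitum. Hippocampi were taken at postnatal day 3 and at week 8. Each of the 4 groups held 2 libraries, so n = 2 per group throughout. Total counts over genes were 14539339 and 17516047 in NS and 17638728 and 18143199 in IUGR at postnatal day 3 (replicates 1 and 2). At week 8 they were 13030277 and 18993050 in NS and 14787742 and 14586285 in IUGR. The series title links restricted fetal growth to the birth of hippocampal neurons, to cognition and to Tet1, a dioxygenase that oxidises 5-methylcytosine in DNA. The comparisons were therefore IUGR against NS at each age, the difference between these effects, normal development in NS, and Tet1 in every group. The labels do not say which libraries came from separate animals or litters. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The list tests with a preset correlation weigh a list's genes against all other genes. Their p-values, however small, do not measure the spread between samples.

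The libraries differed in ways that the treatment groups do not describe. All are labelled male. At postnatal day 3 Xist, the RNA that coats the inactive X chromosome, had 4 and 4998 counts in NS and 81 and 5130 in IUGR (replicates 1 and 2). There, 4 Y-linked genes together had 3783 and 34 counts in NS and 5364 and 74 in IUGR. At week 8 Xist had between 1 and 50 counts, and the Y-linked genes between 2023 and 3936. Rpph1, the RNA component of ribonuclease P, had between 872768 and 1119905 counts in the 4 postnatal day 3 libraries and 1002307 and 959735 in replicate 1 of NS and IUGR at week 8. At postnatal day 3 it was also lower in IUGR by DESeq2 on that age alone (-0.50 ± 0.12, adjusted p = 0.0204, 0.371 with the replicate number as a block), and 9 small non-coding genes, chosen after their values were seen, took 9.02 and 8.06% of counts in NS and 6.54 and 6.27% in IUGR. Rpph1 had 0 and 2 counts in replicate 2 of week 8, where 0 counts allow up to 0.158 CPM, the count scaled by the library total. Replication-dependent histone genes were also lower in replicate 2 than in replicate 1 at week 8, by a median log2 difference of -2.82 in NS and -2.53 in IUGR over 56 genes. Across genes, week 8 libraries of the same number correlated at 0.982 and 0.980 and those of the same group at 0.823 and 0.865. Values within same-numbered pairs of libraries are therefore given beside the pooled ones. Medians within a pair, and between replicates of a group, are of differences in log2(CPM + 1) without TMM scaling. Pooled medians are of TMM-scaled fold changes from edgeR. The added 1 draws low genes toward 0, so sizes on these scales are not directly comparable. Ttr, the transthyretin gene that marks choroid plexus, ranged from 63.1 to 6047 CPM at postnatal day 3, where the groups overlapped. At week 8 it ranged from 22.2 to 6464 CPM, and NS replicate 1 was far above the other 3 libraries. Eef1a1, chosen after its values were seen, took 3.70% of counts in IUGR replicate 1 of week 8. In the other libraries of both ages it took between 0.218 and 0.974%.

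**Figure D1:**
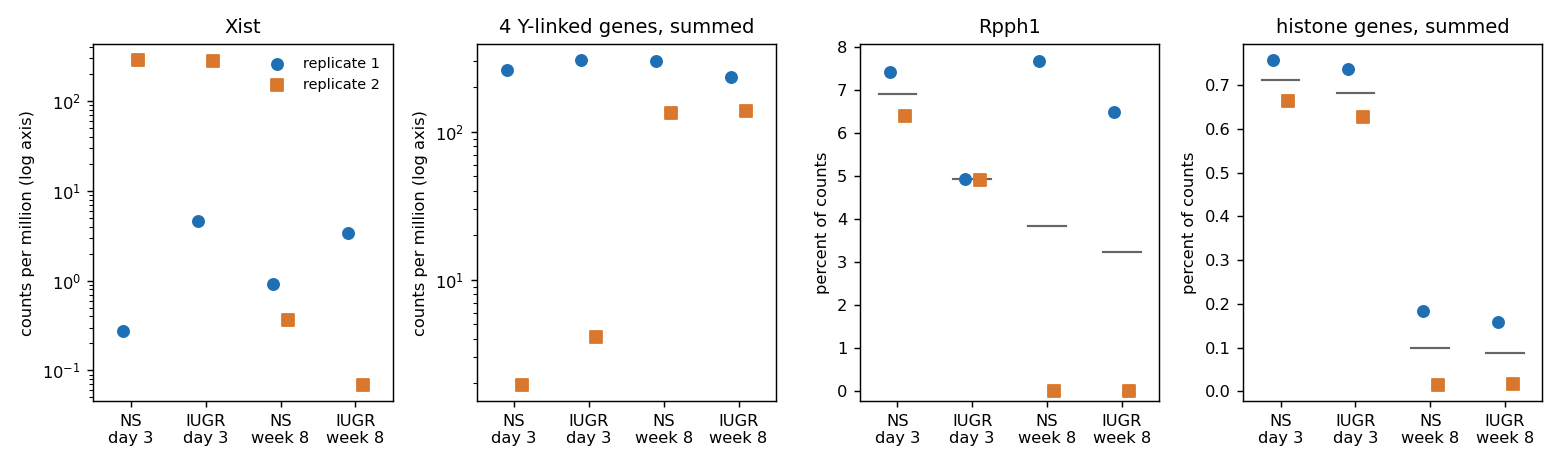
Xist and the summed 4 Y-linked genes in CPM (log axes), and Rpph1 and the histone genes as percent of all counts, in each of the 8 libraries. Points are replicates 1 and 2 of each group and lines are group means in the last panels. Replicate 2 at postnatal day 3 holds the Xist counts, and replicate 2 at week 8 holds 0 and 2 counts of Rpph1.

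The comparison at postnatal day 3 asked how the neonatal hippocampus of IUGR offspring differed from NS. Transcripts of meninges and fibroblasts, the connective tissue that covers the brain, were lower in IUGR: all 26 measured members of the list were below NS, with a median log2 fold change of -0.87. Ogn, a proteoglycan of connective tissue (chromosome 13, 49608046 to 49624501, plus strand), read 41.75 and 33.91 CPM in NS and 12.47 and 12.02 CPM in IUGR (log2 fold change -1.63 ± 0.78, SE). Igf2, an imprinted fetal growth factor (chromosome 7, 142650766 to 142666816, minus strand), read 223.6 and 218.1 CPM in NS and 112.8 and 110.6 CPM in IUGR (-0.98 ± 0.57). The collagen genes Col3a1 (chromosome 1, 45311538 to 45349706, plus strand) and Col6a1 (chromosome 10, 76708792 to 76726168, minus strand) were also lower. Col3a1 read 173.3 and 162.0 CPM in NS against 86.4 and 93.37 CPM in IUGR (-0.90 ± 1.2), and Col6a1 34.87 and 36.65 against 16.38 and 16.7 CPM (-1.11 ± 0.42). Ogn, Igf2 and Col3a1 were chosen after their values were seen, as members with small adjusted p in the fit of this age alone given further on, and Col6a1 by the rule for named genes. By the camera test with a preset correlation between genes the list was called at an adjusted p = 1.29e-20. The adjusted p was 0.521 with an estimated correlation, and over all alternatives it ran from 6.3e-65 to 0.995. The share of small non-coding RNA was lower in the same IUGR libraries, as given above. The call remained with any 1 library left out, and the median was -0.96 within replicate 1 and -0.70 within replicate 2. In the edgeR fit of all libraries no single member passed: 2 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. DESeq2 on this age alone called 13 members, and 6 with the replicate number as a block, as given further on.

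Genes of endothelium and mural cells, which form the blood vessel wall, were lower as well, in 24 of 25 members, with a median of -0.44. Egfl7, an endothelial secreted factor, had a log2 fold change of -0.72 ± 0.26 and Vtn, a pericyte-enriched adhesion protein, -0.85 ± 0.36. Neither passed in the edgeR fit of all libraries. DESeq2 on postnatal day 3 alone called Vtn (-0.86 ± 0.2, adjusted p = 0.0079, 0.46 with the replicate number as a block) and not Egfl7 (0.277). The list was called (adjusted p = 3.28e-12, 0.451 with an estimated correlation, 2.03e-12 to 0.773 over its alternatives), with any 1 library left out too. Its median was -0.26 within replicate 1 and -0.42 within replicate 2. Choroid plexus genes had a median of -0.67 with 22 of 22 members lower but were not called (adjusted p = 0.105), and their median was 1.43 within replicate 1 and -2.28 within replicate 2.

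**Figure D2:**
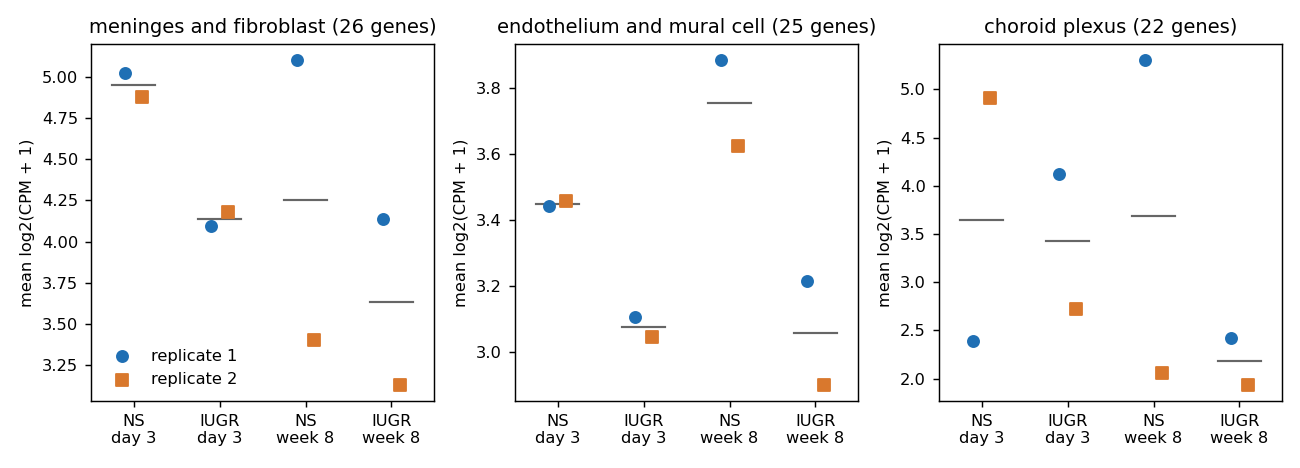
Mean log2(CPM + 1) of the meninges and fibroblast list (26 genes), the endothelium and mural cell list (25) and the choroid plexus list (22) in each library. Points are replicates 1 and 2 and lines are group means. At postnatal day 3 the meningeal level was 5.023 and 4.875 in NS and 4.094 and 4.180 in IUGR, while the choroid plexus level overlapped between the groups.

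Astrocyte genes were lower in 17 of 20 members (median -0.26). Adjusted p was 2.74e-06, or 0.451 with an estimated correlation, and 5.32e-08 to 0.773 over alternatives. Gjb6, a connexin that couples astrocytes, had a log2 fold change of -1.56 ± 0.36 and did not pass in the edgeR fit of all libraries. DESeq2 on this age alone called it (adjusted p = 0.000443, 0.0584 with the replicate number as a block). The astrocyte median was -0.43 within replicate 1 and 0.07 within replicate 2, and the call was lost without NS replicate 1 (median -0.09, adjusted p = 0.0537). Without both replicate 2 libraries of that age the median was -0.47. Interferon and inflammation genes were lower in 19 of 28 members (median -0.31). Adjusted p was 0.000843, or 0.87 with an estimated correlation, and 1.11e-05 to 0.995 over alternatives. The medians were -0.20 and -0.07 within replicates 1 and 2, -0.16 without NS replicate 1 and -0.14 without IUGR replicate 2. Ifi27 and Bst2, both interferon-induced, had -1.11 ± 0.39 and -1.39 ± 0.61. Immediate early genes, which neuronal activity induces, were lower in 19 of 25 members (median -0.21). Adjusted p was 0.00245, or 0.521 with an estimated correlation, and 0.00161 to 0.995 over alternatives. Ier3 was at -1.37 ± 0.39 and Arc at -0.69 ± 0.23. Their medians were -0.11 and -0.15 within replicates 1 and 2, and the call was lost without NS replicate 2 (-0.22, adjusted p = 0.0542) and without both replicate 2 libraries of that age (-0.13, adjusted p = 0.0647).

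Targets of the glucocorticoid receptor were lower in 18 of 28 members, with a median of only -0.08 and a mean of -0.24 (adjusted p = 0.0158, 0.875 with an estimated correlation, 0.0107 to 0.995 over alternatives). Angptl4, an inhibitor of lipoprotein lipase, and the sulfotransferase Sult1a1 had log2 fold changes of -1.12 ± 0.32 and -1.49 ± 0.41. Neither passed in the edgeR fit of all libraries. DESeq2 on this age alone called both (adjusted p = 0.00145 and 0.0028), but not with the replicate number as a block (0.211 and 0.328). The list medians were -0.13 and -0.03 within replicates 1 and 2. Its call was lost without NS replicate 1 (-0.13, adjusted p = 0.151), without IUGR replicate 2 (-0.08, 0.222) and without both replicate 2 libraries of that age (-0.13, 0.144).

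Of the markers of neighbouring brain regions, hypothalamic genes were lower in 13 of 15 members (median -0.38). Adjusted p was 0.00874, or 0.616 with an estimated correlation, and 3.29e-06 to 0.995 over alternatives. Genes of thalamus and habenula were higher in 17 of 19 (median 0.47). Adjusted p was 0.0115, or 0.865 with an estimated correlation, and 4.89e-17 to 0.995 over alternatives. Gpr101 and Baiap3 among the hypothalamic genes had -0.87 ± 0.46 and -0.55 ± 0.54, and Zic1 and Plekhg1 in the thalamic list 0.68 ± 0.37 and -0.33 ± 0.22. Gpr101 and Baiap3 were at -0.41 and -0.35 without NS replicate 1, -0.45 and 0.03 without IUGR replicate 1 and -1.51 and -1.59 without IUGR replicate 2. Neither direction held within both pairs of libraries: the medians within replicates 1 and 2 were -0.68 and 0.04 for hypothalamus and -0.29 and 0.70 for thalamus and habenula. The hypothalamic call was lost without NS replicate 1 (adjusted p = 0.125, median -0.19), NS replicate 2 (0.0526), IUGR replicate 1 (0.8, median -0.06) or week 8 IUGR replicate 1 (0.0527). Its median was -0.88 without IUGR replicate 2 and -1.03 without both replicate 2 libraries. The thalamic call was lost without NS replicate 2 (0.182), had a median of 0.71 without IUGR replicate 1 and turned to lower without IUGR replicate 2 (-0.35, adjusted p = 0.00677) and without both replicate 2 libraries (-0.36, 0.0012).

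Lists for neurogenesis and DNA methylation were not called at this age. The median log2 fold change was -0.05 for neural stem cells and radial glia (adjusted p = 0.862) and 0.11 for intermediate progenitors and immature neurons, with 21 members higher and 5 lower (0.105). It was 0.01 for the cell cycle (0.972) and 0.05 for DNA methylation enzymes and readers (0.975). Among the other uncalled lists, medians and adjusted p were -0.14 and 0.158 for the Notch pathway, -0.06 and 0.367 for the Wnt pathway, -0.03 and 0.777 for the excitatory synapse and 0.07 and 0.331 for GABAergic neurons. They were -0.01 and 0.664 for granule cells and hippocampal fields, -0.1 and 0.105 for oligodendrocyte precursors, -0.15 and 0.104 for myelin and -0.1 and 0.605 for microglia. Ependymal cilia genes had 0.1 and 0.854, blood cells -0.76 and 0.142, striatum 0 and 0.893, and neocortex -0.14 and 0.15. Imprinted genes had -0.08 and 0.145, the insulin and IGF axis -0.07 and 0.0875, and corticosteroid signalling 0.01 and 0.862. Hypoxia response had -0.11 and 0.231, p53 and apoptosis -0.01 and 0.862, and heat shock and unfolded protein 0.02 and 0.898. The nuclear genes of the respiratory chain had -0.05 and 0.836, ribosomal proteins -0.01 and 0.972, histones -0.02 and 0.972 and the sex check 0.19 and 0.641. Median, mean and test differed in sign for the DNA methylation, cell cycle, ependymal, striatal, p53, heat shock and histone lists. Upper-quartile scaling turned the medians of the cell cycle, corticosteroid signalling, striatal and heat shock lists below 0.

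**Figure D3:**
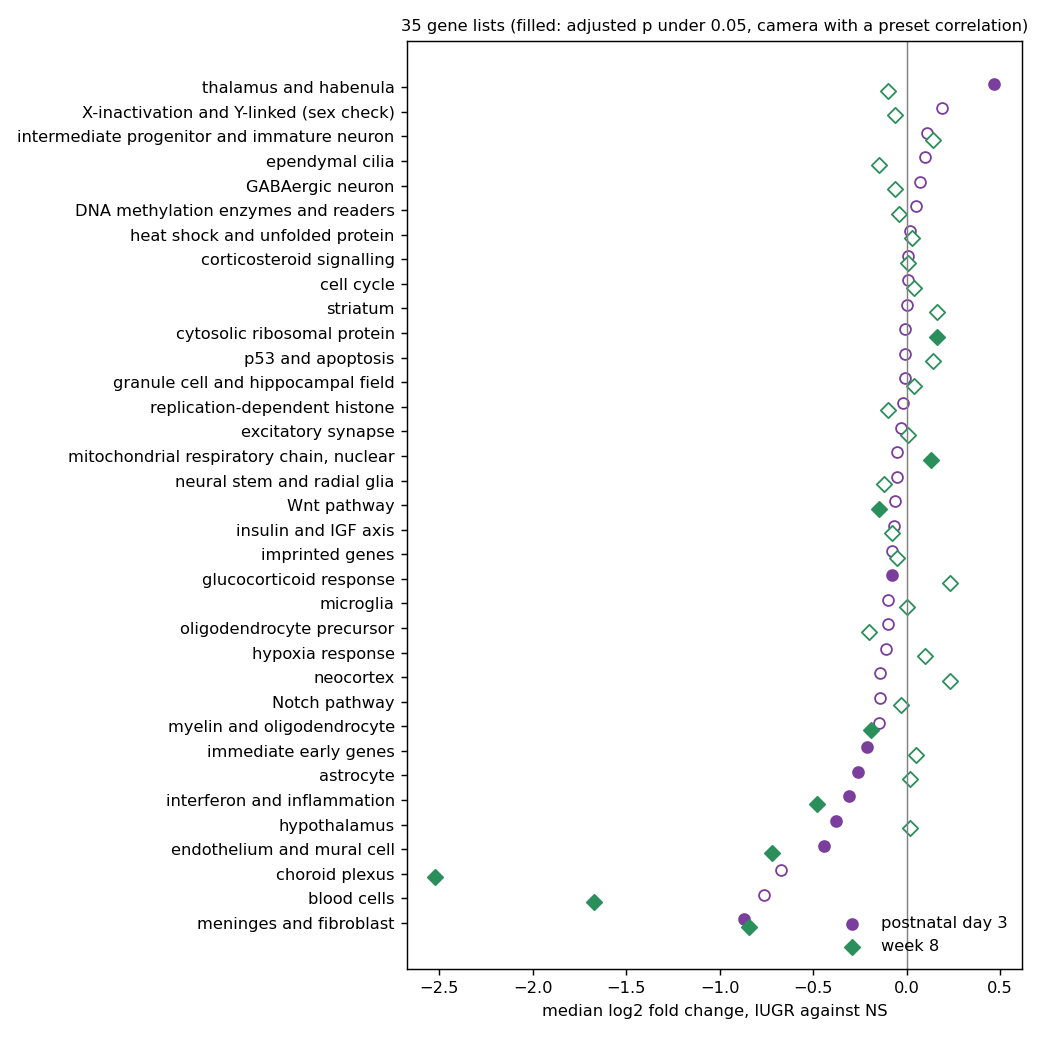
Median log2 fold change, IUGR against NS, of 35 gene lists at postnatal day 3 (circles) and week 8 (diamonds), with filled symbols for an adjusted p under 0.05 by camera with a preset correlation. The meninges and endothelium lists lie below 0 at both ages, and 8 lists are filled at postnatal day 3 and 9 at week 8.

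Gene by gene, 0 of 15999 genes passed in edgeR's quasi-likelihood test over all libraries at postnatal day 3. There, 96 genes had an unadjusted p under 0.05, 15 higher and 81 lower. DESeq2 and limma voom on the same libraries also called 0, with 137 and 90 genes at an unadjusted p under 0.05. In data simulated at these depths the edgeR test recovered 0% of genes changed 2-fold, 27.2% at 4-fold and 75.2% at 8-fold. The 4 libraries of this age were also fitted alone, as planned for edgeR and as added for DESeq2 after the data were seen. Here edgeR called 0 genes (839 at an unadjusted p under 0.05, smallest adjusted p = 0.146) and DESeq2 called 61, with 59 lower in IUGR and 2 higher. In data simulated for those fits edgeR recovered 64.4% of genes changed 2-fold and 95.2% at 4-fold, and DESeq2 66% and 92%, with 10.1% of DESeq2's calls false. The common biological coefficient of variation was 0.154 in the fit of this age alone and 0.374 in the fit of all libraries.

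The genes named next were chosen after their values were seen, among the 61 that DESeq2 called in the 4 postnatal day 3 libraries. With the replicate number as a block DESeq2 called 11 genes, all of them among the 61. They included Igf2, Ogn, Col3a1, Fn1, Col6a1 and Slc6a13 of the meninges and fibroblast list, and Ahnak, Lgals1, Nov and Slc6a20a. The other genes named here lost their call with the block while their log2 fold changes moved little. Among them were Ptgds (-2.39 with the block, adjusted p = 0.328), Efemp1 (-1.87, 0.195), Fmod (-1.61, 0.149), Mgp (-1.71, 0.0812), Avp (-1.54, 0.282), Zic1 (0.68, 0.909) and Cdh8 (0.52, 0.83). Replicate differences at this age correlated across genes at -0.220 between the groups, and the numbers were not taken as pairs. Of the 59 lower genes without the block, 13 belonged to the meninges and fibroblast list, where 0.1 were expected (adjusted p = 3.81e-24 by Fisher's exact test over 35 lists). This test treats genes as independent draws, although all calls come from the same 4 libraries and genes of a list can move together. Its p, here and for the lists below, does not measure the spread between samples. Ogn (-1.64 ± 0.22, DESeq2 adjusted p = 3.35e-10), Igf2 (-0.99 ± 0.13, 3.35e-10) and Col3a1 (-0.91 ± 0.14, 1.86e-07) had the smallest adjusted p. Ptgds, the prostaglandin D synthase of the leptomeninges, had 546.2 and 361.7 CPM in NS and 61.68 and 117.7 CPM in IUGR (-2.35 ± 0.53, adjusted p = 0.00392). Other extracellular matrix genes were Fn1 (-0.88 ± 0.16), Efemp1 (-1.87 ± 0.39), Fmod (-1.61 ± 0.34) and Mgp (-1.69 ± 0.35), with adjusted p between 4.03e-05 and 0.00145. The astrocyte list held 3 of the called genes (Gjb6 and Gja1 among them, 0.08 expected, adjusted p = 0.00105) and the glucocorticoid response list 3 (Angptl4, Sult1a1 and Tgm2, 0.1 expected, adjusted p = 0.00175), but 0 of either list were called with the block. Cldn11, a claudin of myelin and of the arachnoid barrier, had -1.35 ± 0.3 (0.00417), Avp, the vasopressin gene, -1.54 ± 0.34 (0.0028), and Slc17a7, a vesicular glutamate transporter, -0.6 ± 0.16 (0.0474). Sspo, which encodes SCO-spondin, had 89 counts in NS and 3 in IUGR, a ratio of 33.1 with a 95% counting interval of 11 to 164. The 2 higher genes were the transcription factor Zic1, a member of the thalamus and habenula list, and the cadherin gene Cdh8. Zic1 read 31.23 and 34.03 CPM in NS and 50 and 54.84 CPM in IUGR (0.67 ± 0.17, 0.0308), and Cdh8 113.1 and 125.5 against 167.4 and 177.4 CPM (0.52 ± 0.14, 0.0367).

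At week 8 the comparison asked which differences were present in the young adult. Genes of endothelium and mural cells were lower in IUGR in 23 of 25 members, with a median log2 fold change of -0.72. Tie1, a receptor tyrosine kinase of endothelium (chromosome 4, 118471191 to 118490061, minus strand), read 5.833 and 7.792 CPM in NS and 1.42 and 2.194 CPM in IUGR (-1.84 ± 0.37). It was the 1 member that passed when adjusted over the list alone, though not over all genes. Tagln, a smooth muscle actin-binding protein, read 13.43 and 8.898 CPM in NS and 4.801 and 3.634 CPM in IUGR (-1.32 ± 0.35). The list was called (adjusted p = 6.67e-23, 0.156 with an estimated correlation, 7.85e-26 to 0.922 over alternatives), also with any 1 library left out. By edgeR 11 members had an unadjusted p under 0.05, and the median was -0.79 within replicate 1 and -0.70 within replicate 2.

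Choroid plexus genes were lower in 22 of 22 members (median -2.52). Adjusted p was 5.76e-16, or 0.738 with an estimated correlation, and 9.17e-33 to 1 over alternatives. This rested on NS replicate 1, which read 6464 CPM of Ttr where the other 3 week 8 libraries read 47.39, 44.23 and 22.21. Ttr itself (chromosome 18, 20665280 to 20674321, plus strand) had -6.53 ± 2.82, and Trpv4, an ion channel of that epithelium, -2.25 ± 0.79. Without NS replicate 1 the choroid plexus median was 0.11 (adjusted p = 0.575). Meningeal genes were lower in 26 of 26 members (median -0.84). Adjusted p was 1.18e-09, or 0.751 with an estimated correlation, and 2.82e-36 to 1 over alternatives. The transcription factors Foxd1 and Foxc1 were at -1.64 ± 0.68 and -1.2 ± 0.52, and at -0.85 and -0.46 without NS replicate 1. That call was lost without NS replicate 1 (0.51, adjusted p = 0.298) and without IUGR replicate 2 (-0.39, 0.238). The median was -1.60 without NS replicate 2 and -1.82 without IUGR replicate 1, and it was -1.0 within replicate 1 and -0.24 within replicate 2. Interferon and inflammation genes were lower in 26 of 28 (median -0.48). Adjusted p was 4.04e-07, or 0.751 with an estimated correlation, and 1.85e-09 to 1 over alternatives. Irf7, an interferon regulatory factor, read 3.223 and 1.369 against 0.4734 and 0.617 CPM (-1.97 ± 0.61), and the antiviral gene Rsad2 11.9 and 1 against 0.6762 and 0.3428 CPM (-3.55 ± 1.12). These were at -1.26 and -0.91 without NS replicate 1. The call of the interferon list was lost without the same libraries (0.17 and 0.991 without NS replicate 1, -0.07 and 0.766 without IUGR replicate 2), and the medians were -0.44 and -0.24 within replicates 1 and 2, -0.87 without NS replicate 2 and -0.97 without IUGR replicate 1. Blood cell genes were lower in 8 of 8 (median -1.67). Adjusted p was 0.00532, or 0.941 with an estimated correlation, and 9.47e-09 to 1 over alternatives. Blood medians were -1.07 and 0 within replicates 1 and 2, 2.80 without NS replicate 1 (adjusted p = 0.132, fitted with 2 of the 8 members at 0 counts in NS replicate 2) and -0.87 without IUGR replicate 2 (0.939). They were -2.54 without NS replicate 2 and -5.25 without IUGR replicate 1, fitted with 3 of the 8 members at 0 counts in IUGR replicate 2. Alas2, the erythroid enzyme of haem synthesis, had -2.45 ± 1.72 (2.86 without NS replicate 1).

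Myelin and oligodendrocyte genes were lower in 19 of 22 members (median -0.19). Adjusted p was 0.00504, or 0.738 with an estimated correlation, and 6.3e-05 to 1 over alternatives. Nkx6-2 and Myrf, transcription factors of oligodendrocytes, were at -0.6 ± 0.34 and -0.51 ± 0.35. Myrf was at -0.9 without NS replicate 1 and at 0.03 without NS replicate 2. The myelin median was -0.32 within replicate 1 and -0.14 within replicate 2, 0.05 without NS replicate 1 (adjusted p = 0.675) and -0.18 without IUGR replicate 2 (0.459). It was -0.38 without NS replicate 2 and -0.43 without IUGR replicate 1. Wnt pathway genes were lower in 24 of 39 (median -0.15). Adjusted p was 0.00969, or 0.516 with an estimated correlation, and 0.00115 to 0.922 over alternatives. The receptor Fzd5 was at -1.15 ± 0.55 and the ubiquitin ligase Rnf43 at -0.82 ± 0.42. Without NS replicate 1 these were at -0.75 and -0.44, and Fzd5 was at -1.96 without IUGR replicate 1 and -0.63 without IUGR replicate 2. That call was lost without NS replicate 1 (adjusted p = 0.298), NS replicate 2 (0.192), IUGR replicate 1 (0.193), IUGR replicate 2 (0.134) or both replicate 2 libraries (0.0788). Its median stayed below 0 in each of these, at -0.23 without NS replicate 1 and -0.28 without IUGR replicate 2, and was -0.17 and -0.13 within replicates 1 and 2. Ribosomal protein genes were higher in 72 of 79 (median 0.16). Adjusted p was 0.00327, or 0.941 with an estimated correlation, and 4.92e-16 to 1 over alternatives. Nuclear genes of the respiratory chain were higher in 41 of 49 (median 0.13). Adjusted p was 0.00553, or 0.941 with an estimated correlation, and 2.44e-07 to 1 over alternatives. Rpl29 had 0.53 ± 0.22, and Ndufs8 and Ndufs7, subunits of complex I, 0.35 ± 0.19 and 0.37 ± 0.25. Ndufs7 was at 0.61 without IUGR replicate 1 and 0.06 without IUGR replicate 2. Both lists turned to lower without NS replicate 2 (-0.33 for ribosomal proteins, -0.14 for the respiratory chain) and without IUGR replicate 1 (-0.49 and -0.15). They were 0.93 and 0.62 without NS replicate 1, 0.59 and 0.33 without IUGR replicate 2 and 0.10 and 0.09 without both replicate 2 libraries. The ribosomal protein list was still called, in the lower direction (adjusted p = 0.000172 and 0.00236). The respiratory chain list was not (0.175 and 0.591), nor was it called without both replicate 2 libraries (0.188). Ribosomal protein genes differed between the replicates of a group by -1.22 in NS and -1.05 in IUGR. Without TMM scaling, the median of IUGR against NS was 0.01 and 0.24 within replicates 1 and 2 for ribosomal proteins. For the respiratory chain it was 0 and 0.26.

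The remaining 26 lists were not called at week 8, with adjusted p from 0.0522 to 0.997. Median and adjusted p were -0.12 and 0.0746 for neural stem cells and radial glia, 0.14 and 0.669 for immature neurons, 0.04 and 0.997 for the cell cycle and -0.04 and 0.775 for DNA methylation enzymes. They were -0.03 and 0.376 for Notch, 0.23 and 0.119 for the glucocorticoid response, 0.01 and 0.872 for corticosteroid signalling, 0.05 and 0.61 for immediate early genes and 0.01 and 0.458 for the excitatory synapse. GABAergic neurons had -0.06 and 0.655, granule cells 0.04 and 0.669, astrocytes 0.02 and 0.997, oligodendrocyte precursors -0.2 and 0.0669 and microglia 0 and 0.714. Ependymal cilia had -0.15 and 0.45, thalamus and habenula -0.1 and 0.997, striatum 0.16 and 0.376, neocortex 0.23 and 0.0905 and hypothalamus 0.02 and 0.61. Imprinted genes had -0.05 and 0.458, insulin and IGF -0.08 and 0.61, and hypoxia 0.1 and 0.801. The p53 list had 0.14 and 0.0522, heat shock 0.03 and 0.997, histones -0.1 and 0.861 and the sex check -0.06 and 0.997. Medians within 0.05 of 0 were on the other side of 0 or at 0 under upper-quartile scaling for the cell cycle, corticosteroid signalling, immediate early, synapse, granule cell, astrocyte, microglia, hypothalamus and heat shock lists. The cell cycle, corticosteroid signalling, synapse, GABAergic, astrocyte, microglia, heat shock, histone and sex check lists had a median, mean and test of differing sign.

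No single gene passed at week 8 in edgeR's test over all libraries (0 of 15999, 161 at an unadjusted p under 0.05, 38 higher and 123 lower), in DESeq2 (0, 208 unadjusted) or in limma voom (0, 133 unadjusted). The edgeR test recovered 0.4% of genes changed 2-fold, 31.6% at 4-fold and 71.6% at 8-fold in data simulated without the split by replicate number. Of the fits of this age alone, edgeR called 0 genes (29 unadjusted) and DESeq2 called 1, Ttr (-6.54 ± 1.32, adjusted p = 0.0153). Ttr was at -0.45 without NS replicate 1 in the edgeR fit of all libraries, and at -4.08 ± 1.97 (adjusted p = 1) by DESeq2 at this age alone with the replicate number as a block. The replicate number as a block takes up the difference between the libraries numbered 1 and 2. With it DESeq2 called 3 genes, all lower in IUGR and all chosen after their values were seen. These were Fn1, the fibronectin gene (-1.3 ± 0.24, adjusted p = 0.00214), the nuclear long non-coding RNA Neat1 (-1.12 ± 0.24, 0.0325) and the matrix gene Sned1 (-1.66 ± 0.36, 0.0325). In the edgeR fit of all libraries, which has no block, they were at -1.22 ± 0.71, -1.08 ± 0.38 and -1.76 ± 0.97. In that fit the log2 fold change without NS replicate 1 was -0.17 for Fn1 and 0.15 for Sned1, without IUGR replicate 1 it was -2.48 and -3.36, and without IUGR replicate 2 it was -0.56 and -1.02, with Neat1 at -0.71. The edgeR fit with that block called 0, with 603 genes at an unadjusted p under 0.05. In data simulated for the fits with the block edgeR recovered 65.6% of genes changed 2-fold and 95.6% at 4-fold, and DESeq2 46% and 84%.

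The test of the difference between the ages asked which effects of IUGR were larger or smaller at week 8 than at postnatal day 3. It called 9 lists by camera and 0 genes by edgeR (82 at an unadjusted p under 0.05, 94 by DESeq2 and 67 by limma voom, both of which also called 0). Choroid plexus genes had the largest median difference, -1.96 (adjusted p = 5.58e-09, 0.676 with an estimated correlation, 5.54e-37 to 0.982 over alternatives). It was 0.68 without NS replicate 1 of week 8 (adjusted p = 0.203) and -1.19 without NS replicate 1 of postnatal day 3 (0.0545). At that age it was -3.51 without NS replicate 2, -0.88 without IUGR replicate 1 and -4.09 without both replicate 2 libraries, all called. The effect of IUGR on endothelium and mural cell genes was lower by a further -0.39 at week 8 (adjusted p = 0.00632, 0.676 with an estimated correlation, up to 0.982 over alternatives). That call was lost without NS replicate 1 (-0.21, 0.543) or IUGR replicate 2 (-0.18, 0.537) of week 8 or IUGR replicate 1 of postnatal day 3 (-0.24, 0.0652). For meningeal genes the 2 ages did not differ detectably (0.10, adjusted p = 0.261). The 10 genes with the smallest p, 2 of them unnamed gene models, all had an adjusted p of 1. Of the named ones, Gjb6 (1.76 ± 0.49), Sspo (3.80 ± 1.07), Anks4b (4.1 ± 1.11) and Tdrd1 (2.37 ± 0.73) had the higher effect at week 8. The lower effect was that of Tctex1d1 (-3.61 ± 1.05), Ankrd61 (-3.29 ± 0.96), Lpar2 (-1.61 ± 0.49) and the ciliary gene Cfap44 (-1.03 ± 0.32). Gjb6 read 15.75 and 16.61 CPM in NS and 4.195 and 6.779 CPM in IUGR at postnatal day 3, and 94.24 and 89.82 CPM in NS and 71.07 and 129.8 CPM in IUGR at week 8. The other 26 lists had adjusted p from 0.106 to 0.998. In the fit used here 2.8% of genes whose effect differed 4-fold between ages were recovered in simulated data.

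Week 8 was compared with postnatal day 3 in NS as the background of normal development, although age and sequencing batch may coincide. In this comparison 2263 genes passed, of which 1232 rose and 1031 fell (edgeR, adjusted p under 0.05), and 18 of the 35 lists were called. Of these list calls 0 held with an estimated correlation and 10 by fry. The count of genes depended on the libraries: it was 69 without NS replicate 1 and 51 without NS replicate 2 of postnatal day 3, 822 and 824 without IUGR replicates 1 and 2 of that age, 3801 without NS replicate 1 and 1315 without NS replicate 2 of week 8. It was 0 without both postnatal day 3 replicate 2 libraries (1791 at an unadjusted p under 0.05, with other tools not run in that setting) and 6201 without both week 8 replicate 2 libraries. For each list below, the adjusted p with the preset correlation is followed by that with an estimated correlation, the highest of its alternatives, and by the lowest of its alternatives.

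Myelin genes rose together, 21 of 22 passing and 22 when adjusted over the list alone, with a median of 5.31 (adjusted p = 4.73e-35, 0.0664 and 7.45e-71). Mobp, a myelin basic protein of oligodendrocytes, went from 0.5502 and 0.9134 CPM to 508.8 and 365.1 CPM (9.22 ± 0.41, adjusted p = 0.00113). Opalin was at least 176-fold higher (0 counts in the younger libraries, taken as 3 counts per library). Oligodendrocyte precursor genes had a median of 1.15, 4 rising, among them Bcas1 (4.58 ± 0.33), and 1, Vcan, falling (-2.96 ± 0.4). In this list 9 passed when adjusted over the list alone (adjusted p = 0.00405, 0.526 and 5.65e-05), and the median was 1.73 and 0.76 without NS replicates 1 and 2 of week 8. Astrocyte genes rose in 11 of 20 (17 adjusted over the list alone; median 1.53; adjusted p = 2.46e-10, 0.137 and 1.44e-14), among them the glutamate transporter Slc1a2 (3.24 ± 0.33) and Aldoc (2.55 ± 0.33). Microglial genes rose in 10 of 23 (14 adjusted over the list alone; median 1.28; adjusted p = 2.77e-08, 0.257 and 4.53e-10), among them Itgam (2.92 ± 0.34) and P2ry12 (1.92 ± 0.25).

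Of the cell cycle list 29 of 40 fell (37 adjusted over the list alone; median -2.41; adjusted p = 2.05e-24, 0.257 and 3.73e-31), among them Rrm2, a ribonucleotide reductase subunit (-3.55 ± 0.27), the mitotic kinase gene Aurkb (-4.09 ± 0.38) and Mki67 (-3.33 ± 0.32). Of intermediate progenitor and immature neuron genes 11 of 26 fell (14 adjusted over the list alone; median -1.10; adjusted p = 5.38e-10, 0.257 and 5.09e-21), with a median of -1.99 without NS replicate 2 of week 8. Dcx, the doublecortin of migrating neurons, went from 923.2 and 1028 CPM to 23.18 and 22.11 CPM (-5.40 ± 0.35, adjusted p = 0.00219). Dpysl3 was at -5.06 ± 0.27 and Sox11 at -3.83 ± 0.34. Neural stem and radial glia genes were not called as a list (median -0.19, adjusted p = 0.276), while 5 of its members fell, among them Nes (-3.13 ± 0.36) and Vim (-1.55 ± 0.34), and 1 rose. Histone genes had a median of -3.54 with 10 falling (10 adjusted over the list alone; adjusted p = 1.26e-13, 0.532 and 2.93e-53), among them Hist3h2ba (-2.76 ± 0.21). Ribosomal protein genes had a median of -1.17 with 10 of 79 falling (12 adjusted over the list alone; adjusted p = 2.66e-12, 0.557 and 2.51e-17), among them Rplp0 (-2.34 ± 0.29) and Rps26 (-1.5 ± 0.25). Both families were lower in replicate 2 than in replicate 1 at week 8 in NS, by -2.82 and -1.22, and without both week 8 replicate 2 libraries their medians were -2.60 and -0.72. Ribosomal proteins were at -2.06 and -0.73 without NS replicates 1 and 2 of week 8. Histones were lower still without that replicate 1, a fitted median that sets no size because 17 of 56 members had 0 counts in the replicate 2 that was left. Striatal markers had a median of -1.25 with 4 of 19 falling (5 adjusted over the list alone; adjusted p = 0.00123, 0.513 and 1.74e-06, but 0.0514 with a median of -0.67 without NS replicate 2 of postnatal day 3), among them Isl1 (-5.46 ± 1.15) and Adora2a (-2.76 ± 0.58). Isl1 had 5 and 0 counts in NS at week 8, and was at -4.32 without replicate 2. Its fitted value without replicate 1 of week 8, -10.01, rests on a count of 0 and sets no size.

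Among the lists of neurons, those of granule cells and of the excitatory synapse were called higher, neither of them with an estimated correlation, and that of GABAergic neurons was not called (median 0.45, adjusted p = 0.159, 18 members higher and 12 lower). Of granule cell and hippocampal field genes 9 of 23 rose (14 adjusted over the list alone; median 2.07; adjusted p = 4.2e-08, 0.284 and 7.09e-09), among them Rasgrp1 (3.45 ± 0.28) and Spink8 (5.8 ± 0.62). Of excitatory synapse genes 10 of 40 rose (14 adjusted over the list alone; median 1.27; adjusted p = 6.84e-05, 0.48 and 1.74e-07), among them Snap25 (2.61 ± 0.36) and Gria3 (1.69 ± 0.19). The synapse median was 0.53 without NS replicate 2 of week 8. Immediate early genes had 8 rising and 1 falling (11 adjusted over the list alone; median 0.58; adjusted p = 0.000942, 0.284 and 1.19e-05), with Arc at 3.97 ± 0.25 and Junb at 2.31 ± 0.32, and a median of 0.92 without NS replicate 2 of week 8 and 1.27 without NS replicate 2 of postnatal day 3. Glucocorticoid response genes had 7 rising and 1 falling (16 adjusted over the list alone; median 1.53; adjusted p = 2.29e-06, 0.526 and 8.87e-08), among them Fam107a (5.34 ± 0.36) and Glul (2.63 ± 0.28). Corticosteroid signalling had a median of 0.48 and 3 rising genes (3 adjusted over the list alone; adjusted p = 0.0491, 0.284 and 0.000551), among them Hsd11b1, which regenerates active glucocorticoid (3.34 ± 0.44), and the mineralocorticoid receptor gene Nr3c2 (2.62 ± 0.37). That list was at an adjusted p between 0.0551 and 0.14 without any 1 library other than NS replicate 2 of postnatal day 3, with medians of 0.28 without NS replicate 2 of week 8 and 0.27 without NS replicate 1 of postnatal day 3.

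Interferon and inflammation genes had 6 rising and 1 falling (8 adjusted over the list alone; median 1.09; adjusted p = 0.000795, 0.576 and 1.07e-06), among them C4b (3.94 ± 0.45) and H2-K1 (2.11 ± 0.28), but a median of 0.54 and an adjusted p of 0.216 without NS replicate 1 of week 8. Hypoxia response genes rose in 8 of 24 (12 adjusted over the list alone; median 0.55; adjusted p = 0.0182, 0.257 and 0.00656), among them Aldoa (2.31 ± 0.44) and Ndrg1 (1.04 ± 0.19). The p53 and apoptosis genes had 4 falling and 1 rising (7 adjusted over the list alone; median -0.57; adjusted p = 0.016, 0.284 and 0.00189). Without NS replicate 1 of week 8 these lists were at 0.0533 and 0.0515. Imprinted genes had 9 falling and 3 rising (21 adjusted over the list alone; median -0.58; adjusted p = 0.0143, 0.557 and 0.00421), among them H19 (-7.45 ± 1.03) and Mkrn3 (-4.45 ± 0.33). Their median was -1.19 and -0.27 without NS replicates 1 and 2 of week 8, and -0.26 without both week 8 replicate 2 libraries (adjusted p = 0.0506). With the replicate block it was -0.51 and not called (0.137). DNA methylation enzymes were not called as a list (median -0.03, adjusted p = 0.723). Of these, 4 members fell, among them Uhrf1 (-3.6 ± 0.29) and the maintenance methyltransferase Dnmt1 (-1.47 ± 0.22), while 3 rose, among them Zbtb4 (1.58 ± 0.2), and 11 passed when adjusted over the list alone. Every gene named as rising or falling in this comparison had an adjusted p between 0.00113 and 0.05. Of 49 such genes, Tet1 among them, all 49 kept their direction in each alternative. Fewer still passed in some: 15 and 13 without NS replicates 1 and 2 of postnatal day 3, 41 without either IUGR replicate of that age, 0 without both replicate 2 libraries of that age and 42 without NS replicate 2 of week 8. The largest changes under the rule for named genes also held Krt9 and Pla2g2f, at least 19 and 17.9-fold higher, Akr1c19, at least 28.8-fold lower, and Sec14l5, 384-fold higher (interval 68.6 to 15200). Lhx8, Tfap2d and P2rx2 were lower by ratios of 182 (32.2 to 7220), 118 (20.8 to 4700) and 107 (29.4 to 892).

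The other uncalled lists of this comparison had medians and adjusted p of 0.13 and 0.955 for Notch, -0.07 and 0.497 for Wnt and 0.23 and 0.365 for endothelium. They were 0.19 and 0.847 for choroid plexus, -0.5 and 0.171 for ependymal cilia, -0.32 and 0.171 for meninges, 0.89 and 0.632 for blood cells, -0.29 and 0.49 for thalamus and habenula and -0.24 and 0.978 for neocortex. Hypothalamus had -1.02 and 0.219, insulin and IGF 0.1 and 0.843, heat shock 0.06 and 0.474, the respiratory chain -0.13 and 0.759 and the sex check 0.81 and 0.723. The Notch, blood cell, neocortex, insulin and sex check lists had median, mean and test of differing sign, and heat shock was below 0 under upper-quartile scaling.

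**Figure D4:**
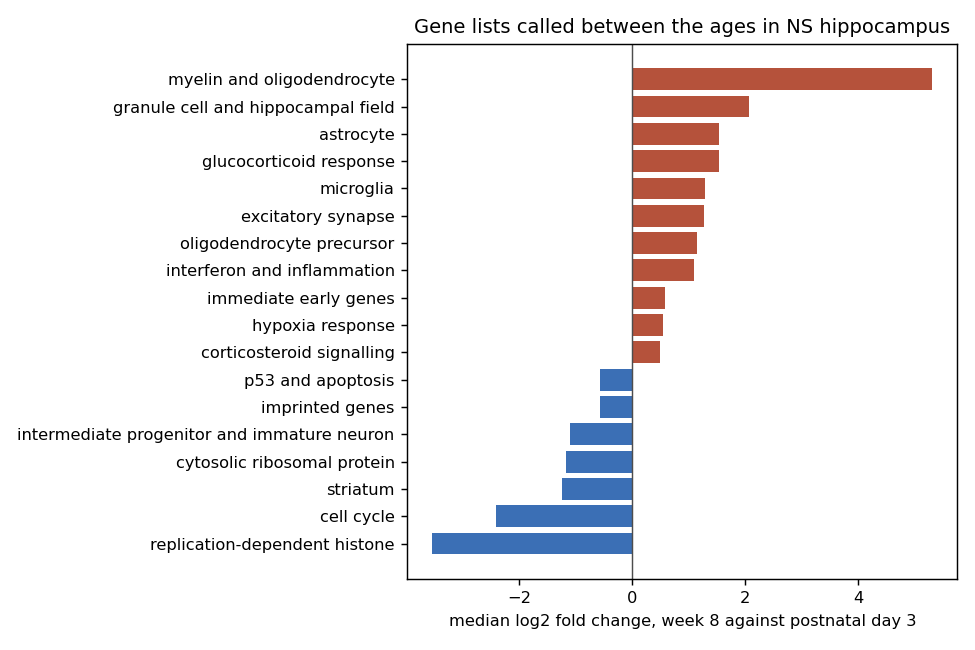
Median log2 fold change, week 8 against postnatal day 3 in NS, of the 18 lists called by camera with a preset correlation. Bars start at 0, with myelin highest at 5.31 and histones lowest at -3.54.

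Tet1, the gene in the series title (chromosome 10, 62804570 to 62908996, minus strand), did not differ detectably between IUGR and NS at either age. It read 84.25 and 87.98 CPM in NS and 87.7 and 98.82 CPM in IUGR at postnatal day 3 (0.11 ± 0.52, adjusted p = 1). At week 8 it read 29.09 and 11.16 CPM in NS and 27.05 and 11.38 CPM in IUGR (0.02 ± 0.53, adjusted p = 1), and at neither age did it pass when adjusted over its list alone. Its week 8 effect was 0.84 without NS replicate 1, -0.51 without NS replicate 2, -0.75 without IUGR replicate 1 and 0.51 without IUGR replicate 2. Such fits set unequal replicate numbers against each other, and Tet1 differed by number in both groups at week 8, as the CPM show. By DESeq2 at week 8 alone with the replicate block the effect was 0.02 ± 0.32. In NS the log2 change of Tet1 from postnatal day 3 to week 8 was -2.08 ± 0.54, with an adjusted p of 0.05 as rounded, just under the threshold. It was -1.55 without both week 8 replicate 2 libraries. The call was kept by DESeq2 (-2.07, adjusted p = 0.00185), by limma voom (-2.27, 0.0299) and by edgeR with the replicate block (-1.52, 0.000847). That call was lost without NS replicate 1 (adjusted p = 0.203), NS replicate 2 (0.21), IUGR replicate 1 (0.105) or IUGR replicate 2 (0.105) of postnatal day 3 or NS replicate 2 of week 8 (0.122, log2 change -1.56), without both postnatal day 3 replicate 2 libraries (0.446) and under upper-quartile scaling (0.0599). Nr3c1, the glucocorticoid receptor gene (chromosome 18, 39410545 to 39519421, minus strand), read 56.4 and 55.26 CPM in NS and 52.67 and 42.27 CPM in IUGR at postnatal day 3 (-0.23 ± 0.59). At week 8 it read 181.1 and 72.45 CPM in NS and 191.3 and 62.52 CPM in IUGR (0.08 ± 0.59). Its adjusted p was 1 at both ages, and 0.213 for its change from postnatal day 3 to week 8 in NS (1.21 ± 0.6), which was 0.40 without NS replicate 1 of week 8. At week 8 its IUGR effect was 0.87 without NS replicate 1, -0.42 without NS replicate 2, -0.95 without IUGR replicate 1 and 0.67 without IUGR replicate 2. Those fits also set unequal replicate numbers against each other, and by DESeq2 at that age alone with the block the effect was 0 ± 0.23.

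**Figure D5:**
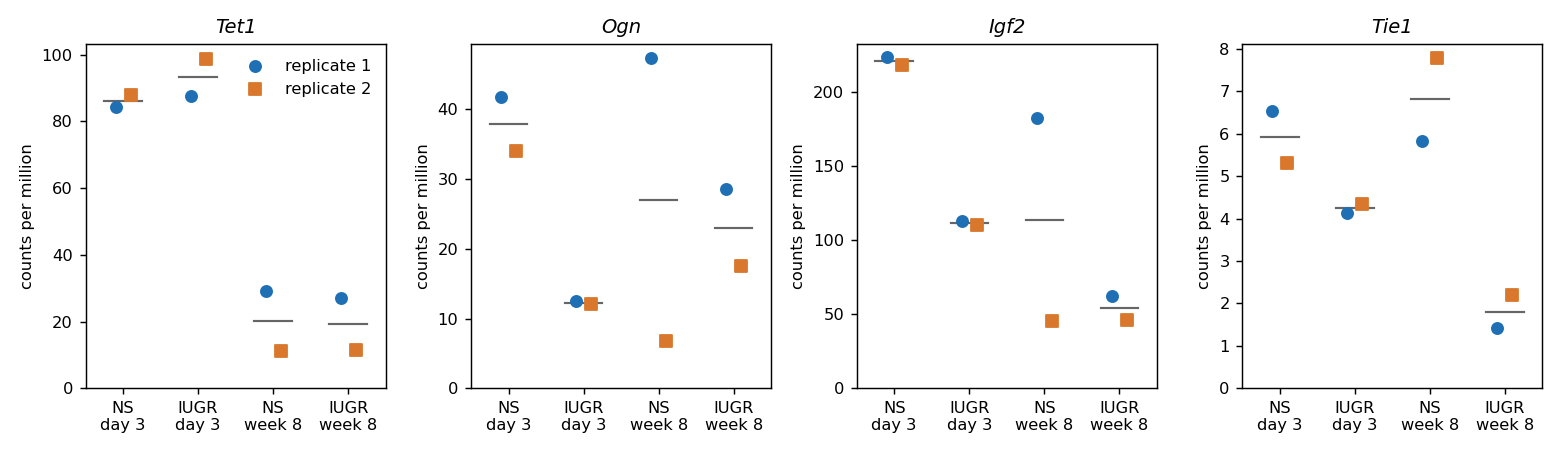
CPM of Tet1, Ogn, Igf2 and Tie1 in each library, with replicates 1 and 2 as points in each group. Ogn and Igf2 at postnatal day 3 and Tie1 at week 8 are lower in both IUGR libraries than in both NS libraries, while Tet1 overlaps between NS and IUGR at each age. Of genes with a mean of at least 1 CPM, 36.6% of 14507 did not overlap at postnatal day 3 and 12.2% of 14419 at week 8. By chance 33.3% would not overlap.

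The overlap of calls between the ages asked whether the same genes differed at both. With 0 calls at each age in the fit of all libraries, none were shared and no Fisher test could be made. DESeq2 on each age alone shared 0 genes between its 59 lower calls at postnatal day 3 and its 1 at week 8. With the replicate block in DESeq2, a fit added after the data were seen, 1 gene was shared, Fn1. There were 11 and 3 lower calls of 18649 genes tested at both ages, and 0.00177 shared genes were expected (p = 0.00177, Fisher's exact test, two-sided). This p rests on 1 gene and treats genes as independent, so it does not show that an effect was shared between the ages. At week 8 Fn1 was at -0.17 without NS replicate 1 and at -2.48 without IUGR replicate 1 in the fit of all libraries.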

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

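The tests for another library preparation and for depth were chosen after the result was seen, as was leaving out both week 8 replicate 2 libraries, and the prediction for GC content was written before its test.

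For 9 gene lists the effect of IUGR on the hippocampus differed between week 8 and postnatal day 3 by a test of the difference itself (camera with a preset correlation), while no list differed with an estimated correlation. Astrocyte genes had a median difference of log2 fold changes of 0.26 (adjusted p = 0.00177, 0.676 with an estimated correlation, 1.32e-05 to 0.982 over alternatives). Glucocorticoid response genes had 0.37 (0.00177, 0.924, 9.43e-14 to 0.982). Immediate early genes had 0.26 (0.00575, 0.676, 8.77e-05 to 0.982) and hypothalamic markers 0.49 (0.0108, 0.676, 6.82e-05 to 0.983). In the fit of all libraries these lists were lower in IUGR at postnatal day 3 and less so or not at week 8. The effect of IUGR was higher at week 8 than at postnatal day 3 for neocortex markers (0.28, adjusted p = 0.00988, 0.676 with an estimated correlation). So it was for nuclear genes of the respiratory chain (0.19, 0.0108, 0.924) and ribosomal protein genes (0.17, 0.0126, 0.924). It was lower for choroid plexus genes (-1.96, adjusted p = 5.58e-09, 0.676 with an estimated correlation) and endothelium and mural cell genes (-0.39, 0.00632, 0.676). The highest adjusted p over alternatives was 0.982 for each of these lists. These values compare effects of IUGR, not levels at the 2 ages. They did not all hold within same-numbered pairs. Within replicates 1 and 2 of week 8 the medians were -0.22 and 0.45 for the glucocorticoid response and 0.21 and -0.31 for neocortex. They were -0.08 and -0.05 for astrocytes, 0.13 and -0.06 for immediate early genes and -0.07 and 0 for hypothalamus. Within replicate 2 of postnatal day 3 the astrocyte and hypothalamic medians were 0.07 and 0.04. No member of the 9 lists passed when adjusted over the list alone.

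Each of the 9 calls was lost or turned when some 1 library was left out, and 3 to 7 of them stayed in each such fit. Replicate differences at week 8 correlated across genes at 0.884 between the groups, so a fit without 1 library of that age sets unequal replicate numbers against each other, and ribosomal protein genes differed between those numbers by -1.22 in NS and -1.05 in IUGR. With the replicate block 7 of the 9 calls stayed, and neocortex (median 0.15, adjusted p = 0.0597) and hypothalamus (0.40, 0.097) were lost.

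Some lost calls kept the size of the median and others did not. Without NS replicate 1 of week 8 the median and adjusted p were 0.34 and 0.11 for astrocytes, 0.46 and 0.126 for neocortex, 0.14 and 0.822 for the glucocorticoid response, 0.10 and 0.822 for immediate early genes, 0.68 and 0.203 for choroid plexus and -0.21 and 0.543 for endothelium. Without IUGR replicate 2 of week 8 they were 0.22 and 0.0776 for astrocytes, 0.47 and 0.121 for hypothalamus, -0.45 and 0.0714 for the glucocorticoid response, 0.08 and 0.412 for immediate early genes and -0.18 and 0.537 for endothelium. Without IUGR replicate 1 of week 8 the ribosomal protein difference was -0.51 (0.00714), the respiratory chain -0.10 (0.755), neocortex -0.31 (0.681) and hypothalamus 0.05 (0.615), and without NS replicate 2 of week 8 they were -0.35 (0.000558), -0.18 (0.289), 0.22 (0.106) and 0.12 (0.983). Medians also moved where the call stayed, to 1.07 for the glucocorticoid response and 0.11 for immediate early genes without IUGR replicate 1 and to 0.85 and 0.75 without NS replicate 2 of week 8. Without NS replicate 1 of week 8 they moved to 1.29 for hypothalamus, 0.92 for ribosomal proteins and 0.68 for the respiratory chain, and without IUGR replicate 2 to 0.62 and 0.46 for the last 2 and 0.47 for neocortex.

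At postnatal day 3, leaving out NS replicate 1 gave 0.09 and 0.126 for astrocytes, -1.19 and 0.0545 for choroid plexus, 0.11 and 0.183 for ribosomal proteins, 0.10 and 0.129 for the respiratory chain and 0.30 and 0.12 for hypothalamus, while immediate early genes stayed called at 0.40. NS replicate 2 gave 0.07 and 0.0552 for immediate early genes, 0.02 and 0.31 for neocortex and 0.30 and 0.0863 for hypothalamus. IUGR replicate 1 gave 0.19 and 0.0574 for astrocytes, -0.24 and 0.0652 for endothelium, 0.29 and 0.0505 for neocortex and 0.04 and 0.937 for hypothalamus. IUGR replicate 2 gave 0.13 and 0.198 for ribosomal proteins and 0.19 and 0.056 for the respiratory chain, with hypothalamus still called at 0.90.

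Separately, the replicate 2 libraries of week 8 stand apart from replicate 1 in both groups. Without both of these libraries week 8 holds 1 library per group, so that fit cannot show whether the calls above depend on them. The NS library left is replicate 1, with Ttr at 6464 CPM. In that fit the median difference was 0.01 for the glucocorticoid response, 0.31 for hypothalamus, 0.41 for immediate early genes and 0.46 for neocortex. The tables argue against lower depth, since the totals were 1.46 and 0.986 times those of replicate 1, and against a GC trend as the whole cause, since the histone genes were still at -3.95 in NS and -3.43 in IUGR after the trend was removed, compared with -3.05 and -2.78 before. A preparation that keeps few transcripts without a poly(A) tail may account for it: replication-dependent histone mRNAs, which lack that tail, were lower by those medians over 49 genes, and Rpph1 had 0 and 2 counts. The ribosomal RNA precursor Rn45s went both ways at week 8. It took 0.334 and 0.0549% of counts in replicates 1 and 2 of NS, but 0.275 and 0.978% in those of IUGR. The labels describe 1 protocol for all libraries, so such a preparation stays a hypothesis drawn from the same data. No group of the design separates these replicates, so no biological explanation was tested.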

How the results depend on the processing

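The fits of DESeq2 and of blocked models on each age alone, the omission of both replicate 2 libraries of an age and the crossed numbers were chosen after the data were seen. Of the genes named, 847 of the gene values under planned settings, 813 with 1 library left out and 344 under added settings kept their direction and side of the threshold, and of the called lists 68, 281 and 94 values did. Calls were lost in 4, 93 and 49 gene values and 81, 52 and 43 list values, and gained in 1 planned and 37 added gene values. Where a value below differs from the report the cause was not tested, except that an estimated correlation widens the list test by construction.

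Counts of called genes at postnatal day 3 were 0 in all planned settings, 61 by DESeq2 on that age alone and 11 with its replicate block, and at week 8 they were 0, 1 and 3. For development in NS (2263) DESeq2 called 3922 genes, the replicate block 5049, the fit without both week 8 replicate 2 libraries 6201 and that without both postnatal day 3 replicate 2 libraries 0, and with 1 library left out the count ran from 51 to 3801. The overlap between ages was 1 gene with the DESeq2 block and 0 otherwise.

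Of 35 lists, 8 were called at postnatal day 3. The total was 0 with an estimated correlation (also with that age alone, with or without the block) and by fry, 13 with the replicate block, 13 with that age alone, 15 with that age alone and the block, 13 without both postnatal day 3 replicate 2 libraries, and 7 to 13 with 1 library left out. Of the 8 first called, 8 stayed with the block, with that age alone and with both, 5 without those 2 libraries, and 5 to 8 with 1 library left out. At week 8 the 9 calls became 0 with an estimated correlation (also with that age alone) and by fry, 14 with that age alone, 14 without both week 8 replicate 2 libraries and 8 to 14 with 1 library left out, of which 9, 7 and 3 to 9 were among the first 9. For the difference between ages the 9 calls became 0 and 0, 12 without both week 8 and 9 without both postnatal day 3 replicate 2 libraries (7 of the first 9 in each), and 6 to 13 with 1 library left out (3 to 7). For development the 18 became 0 with an estimated correlation, 10 by fry and 17 to 19 with 1 library left out (14 to 17 of the first 18).

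The replicate block called 0 genes at postnatal day 3 (495 at an unadjusted p under 0.05), 0 at week 8 (802) and 0 for the difference (413) by edgeR, and 11, 10 and 18 lists at week 8, for the difference and for development (9, 7 and 17 of those first called). Replicate differences correlated across genes at 0.884 between the groups at week 8 and at -0.220 at postnatal day 3. With the numbers crossed at postnatal day 3, edgeR called 0 genes, with 604 at an unadjusted p under 0.05. The common biological coefficient of variation was 0.374 without the block and 0.164 with it.

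Directions turned as follows. The thalamus list at postnatal day 3 was at -0.36 without both replicate 2 libraries of that age, and the glucocorticoid difference between ages at 0.01, with its test turned to lower, without both week 8 replicate 2 libraries. Tet1 at week 8 was at -0.04 under upper-quartile scaling and -0.02 without both week 8 replicate 2 libraries, and Nr3c1 at week 8 at 0 in the DESeq2 and edgeR fits of that age with the block. With 1 library left out, medians at postnatal day 3 ran from -0.35 to 0.71 for thalamus and from -0.88 to -0.06 for hypothalamus. At week 8 they ran from -3.4 to 0.11 for choroid plexus, -1.82 to 0.51 for meninges, -5.25 to 2.8 for blood, -0.97 to 0.17 for interferon, -0.15 to 0.62 for the respiratory chain and -0.49 to 0.93 for ribosomal proteins. For the difference between ages they ran from -0.45 to 1.07 for the glucocorticoid response, -3.51 to 0.68 for choroid plexus, -0.31 to 0.47 for neocortex, 0.04 to 1.29 for hypothalamus, -0.18 to 0.68 for the respiratory chain and -0.51 to 0.92 for ribosomal proteins. Single genes ran from -1.59 to 0.03 for Baiap3 at postnatal day 3 and, at week 8, from -0.9 to 0.03 for Myrf, -5.27 to 2.86 for Alas2, -3.36 to 0.15 for Sned1, -0.75 to 0.84 for Tet1 and -0.95 to 0.87 for Nr3c1. No called list changed the sign of its median under the RLE or upper-quartile scaling (0 of 44). The fits of each age alone have no counterpart for comparisons across ages.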

Other observations

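The tests on sex, on the meningeal genes and on the later direction of the lower genes were chosen after the result was seen, except that the prediction for genes escaping X inactivation was written before.

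Genes that DESeq2 called lower in IUGR at postnatal day 3, fitted alone, and that were chosen after their values were seen, with no test of a group, included Mrc1 (-0.90 ± 0.19, adjusted p = 0.00237) and Stab1 (-1.11 ± 0.25, 0.00393), scavenger receptors of macrophages at the borders of the brain. Neither was called with the replicate block (0.195 and 0.282), and the microglia list was not called at that age (median -0.1, adjusted p = 0.605) and had medians of -0.35 and 0.22 within replicates 1 and 2. The transporter genes Slc6a13, for GABA and taurine and a member of the meninges list (-1.30 ± 0.23, adjusted p = 5.23e-05), and Slc6a20a, for proline (-1.59 ± 0.28, 4.03e-05), were called with the block too (0.0356 and 0.0405). The edgeR fit of the same libraries called none of these.

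Both postnatal day 3 replicate 2 libraries, labelled male, read Xist and almost no Y-linked transcripts. The tables argue against a mixture of male and female tissue, since the Y-linked CPM of replicate 2 was 0.746% of replicate 1 in NS and 1.34% in IUGR while Xist was high. Tissue of female pups is a candidate explanation: 4 genes that escape X inactivation had a median log2 difference between replicate 2 and replicate 1 of 0.452 in NS and 0.427 in IUGR, with 3 of the 4 higher in both groups and Ddx3x at -0.14 in IUGR. The labels give no female samples, and both groups hold 1 such library, so the comparison of IUGR with NS is balanced for it.

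Meningeal and fibroblast genes were lower in IUGR at postnatal day 3, in 26 of 26 members. The tables argue against a difference in attached choroid plexus, because the meningeal median was -0.96 in the pair of libraries where choroid plexus genes were higher in IUGR, and against sex, because it was -0.96 and -0.7 within same-numbered pairs. Whether less meningeal tissue was taken with the IUGR hippocampi cannot be told apart from lower expression in that tissue. The fold changes of the members, from -0.159 to -1.81, had an SD of 0.408 against a root mean square SE of 0.228, a ratio of 1.79, but neither dissection nor the number of cells was measured. An effect of prenatal dexamethasone on meningeal cells stays open and untested.

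Of the 59 genes lower at postnatal day 3, 54 were also lower in IUGR at week 8 within replicate 1 (91.5%, against 58.2% of all genes, median -0.863), but 34 within replicate 2 (57.6% against 54.8%, median -0.18). The replicate 1 pair holds NS replicate 1, where the mean log2(CPM + 1) of meningeal genes was 5.10 and of choroid plexus genes 5.30, against 3.13 to 4.14 and 1.93 to 2.43 in the other 3 week 8 libraries. The smaller excess was 2.87 percentage points, so these libraries do not tell whether the difference may persist to week 8.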
